A study of Arabidopsis thaliana with 12 samples.

How the data were processed

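Transcript levels were measured on 12 Affymetrix ATH1 arrays, 3 for wild-type Arabidopsis thaliana of the Col-0 ecotype and 3 for each of the lines gra1-D, gra2-D and gra3-D. Seedlings grew on MS medium at 22 °C with 16 h of light and 8 h of dark, and their vegetative part was taken at stage 1.03. Per the labels, total RNA was purified with RNeasy columns, labelled with biotin and hybridized by the standard Affymetrix procedure, and each array stands for 1 biological replicate.

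The authors deposited 1 table of log2 expression values, which they had background-corrected, normalized between arrays and summarised over probes with RMA (version not stated). The log2 scale was read from the values, whose array medians lie between 6.36 and 6.43. The table holds 20777 AGI loci with 1 row per locus, so probes had been regrouped by locus under a definition that the files do not state. The choices made before the data were examined had assumed several probe sets per gene, and the step of choosing 1 of them was not needed. The files name no genome build. Loci were ordered by their names, and symbols came from a gene table of assembly TAIR10.1, which matched 20508 loci and gave 8945 of them a symbol other than the locus. No coordinates are given. No 2 arrays held the same values, and arrays carry no read depth, so the number of arrays limits the precision.

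Group means of the 4 groups were fitted together with limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 8 residual degrees of freedom per locus and a prior of 5.28. The median SE of a log2 fold change was 0.0886. The 6 contrasts were each mutant against wild type and each mutant against another, two-sided, with p-values adjusted by Benjamini-Hochberg within each contrast. A locus was called changed at an adjusted p under 0.05. No filter on low values was applied to this test. A group mean log2 value under 5 was taken as close to background, a level chosen after the values were seen, and a difference from such a group as a lower bound. Where both groups lay under 5, no bound holds and the size of the difference is uncertain. Replicate numbers were not used as a block, since the labels do not say that equal numbers were grown or processed together. The values later showed such a pairing, except for replicates 1 and 3 of gra3-D. Variation shared by equal numbers therefore stayed in the residual of this fit, and counts with a block are given beside it.

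Raised or lowered chromosome segments were sought by circular binary segmentation (own code, Python 3.11.15, numpy 2.4.6, numba 0.67.0) on loci with a mean log2 value of at least 6 over all arrays, in the order of their names. Fold changes were clipped at plus or minus 1, a segment held at least 20 genes, and a split was kept when fewer than 1% of 1000 random gene orders reached its largest statistic. A segment was called when its median differed from that of all other genes by 0.2 or more. Per array, the shift of a segment was the median over its expressed genes of the log2 value minus the wild-type mean, less the same median over expressed genes outside every segment. Groups were compared by exact two-sided permutation tests. Segment genes were tested against the segment's own median log2 fold change with the limma SE, adjusted over the segment's expressed genes.

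Lists of genes, 29 in all with 388 of 431 members on the table, were tested against all other genes with limma's camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. Fry tested each list against no change. They cover D-type cyclins, mitotic genes, DNA replication genes, CDK inhibitors, leaf size regulators, cell wall loosening genes, photosynthesis genes, auxin response genes, cytokinin response genes, gibberellin and brassinosteroid genes, cold and drought genes, salicylate defence genes, jasmonate genes, heat shock genes, circadian clock genes, shade and light signalling genes, senescence and starvation genes, flavonoid genes, aliphatic glucosinolate genes, DNA damage response genes, leaf polarity genes, shoot meristem markers, stomatal lineage markers, trichome and epidermal patterning genes, vascular markers, root markers, floral markers, seed storage markers and the 7 loci that the gene table names as cytosolic ribosomal proteins.

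The comparisons, tests, lists and the rule for named genes were fixed before the data were examined. The rule names, for each mutant against wild type, the 8 largest rises and 8 largest falls past the threshold outside every segment with all 3 mutant arrays on 1 side of all 3 wild-type arrays. It also names the 5 largest rises in the segment, the first and last gene of each segment, up to 4 members of each list (2 where a comparison would hold over 30 genes) and always ANT, CYCD3;1, CYCB1;1, GRF2 and AN3. For the 3 mutants together it names the 8 largest mean rises and falls past the threshold in all 3, for mutant against mutant the 3 largest in each direction outside the segments, and for segment genes the 4 furthest on each side of the segment median. Gene symbols follow the gene table.

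The steps were tested on simulated data: independent normal values with the wild-type means and residual SDs of the loci for limma, camera and departures, and real fold changes of gra1-D shuffled along chromosome 2, with a raised block added, for the segmentation. For gra1-D against wild type on 20777 loci, limma recovered 72.8% of changes of 0.5 log2 and 97.7% of changes of 1 log2 over 10 simulations, with 4.96% false calls. Camera found a list of 12 genes lowered by 0.3 log2 in 10 of 10 simulations and called 0 of 280 unchanged lists. Simulated list members were independent, so false calls of lists with correlated members stay untested. Estimated correlations within the real lists ran from -0.058 (trichome and epidermal patterning genes) to 0.77 (aliphatic glucosinolate genes). Among 383 segment genes, 94% of departures of 0.7 log2 were found, with 1.57% false calls. All simulated segment genes were raised by the same amount, whereas the real rise varied with signal level. That rate of false calls therefore may not hold for the real departures. Segmentation of 1689 genes of chromosome 2 found a block of 200 genes raised by 1 log2 in 10 of 10 simulations at its true bounds and split 0 of 20 chromosomes without a block.

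Alternatives were fixed for the normalization (quantile normalization once more, arrays centred on their medians or on chromosomes without a segment), low values, the variance model, the replicate block, the arrays in the fit, a fold minimum of 1.5, the segmentation settings, the summary of the segment, the set test and each array left out in turn. A replicate block fitted without the gra3-D arrays was added after seeing the data. Figures were drawn with matplotlib 3.10.9 and tables handled with pandas 2.3.3.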

Results

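ATH1 arrays measured transcript levels in wild-type Arabidopsis thaliana and in the lines gra1-D, gra2-D and gra3-D, grandifolia mutants that the series title links to a chromosomal duplication. Each of the 4 groups held 3 arrays, 1 per biological replicate. Every array gave log2 values for 20777 gene loci, with medians from 6.36 to 6.43. Correlations over genes, which are not independent replicates, ran from 0.996 to 0.997 between arrays of a group and from 0.991 to 0.998 between groups. The first principal component held 33.3% of the variance, with wild-type arrays between -23.8 and -21.5 and mutant arrays between 3.97 and 13.0.

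The first question was where along the chromosomes expression differed by position in each mutant. On chromosome 4, one long run of neighbouring genes was higher in every mutant than in wild type and reached the last locus of that chromosome on the array. It began at DHS2 (AT4G33510), a gene of aromatic amino acid synthesis, in gra1-D and held 561 loci, 383 of them expressed at a mean log2 value of at least 6. It began at AT4G31170 in gra2-D, with 763 loci and 520 expressed, and at AUR1 (AT4G32830), which encodes a mitotic Aurora kinase, in gra3-D, with 622 loci and 426 expressed. Median expression of the run stood at 1.87-fold the wild-type level in gra1-D (log2 shift 0.90 ± 0.011, SD, n = 3), at 1.88-fold in gra2-D (0.91 ± 0.010) and at 1.88-fold in gra3-D (0.91 ± 0.0039). A doubling corresponds to a log2 shift of 1 and a 1.5-fold level to 0.585.

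Of the expressed genes in the run, limma called 368 of 383 (96.1%) higher in gra1-D, 504 of 520 (96.9%) in gra2-D and 414 of 426 (97.2%) in gra3-D. It called 0 lower, against 0, 1 and 0 at an unadjusted p under 0.05. No other segment was called on any of the 5 nuclear chromosomes in the mutants. Each exact permutation test of 3 mutant against 3 wild-type arrays, two-sided, gave p = 0.1, the smallest value that 20 splits allow, and every mutant array lay above every wild-type array. For the last expressed gene before the run, log2 changes were -0.08 ± 0.07 (SE) for AT4G33500 in gra1-D, 0.11 ± 0.12 for DCAF1 (AT4G31160) in gra2-D and -0.08 ± 0.11 for VTE1 (AT4G32770), a tocopherol synthesis gene, in gra3-D. The first genes of the run rose by 0.74 ± 0.07 (DHS2), 0.92 ± 0.07 (AT4G31170) and 0.46 ± 0.11 (AUR1). The last expressed gene, AT4G40080, stood at 0.42 ± 0.11, 0.36 ± 0.11 and 0.52 ± 0.11, with adjusted p = 0.0459, 0.0581 and 0.0134. The AUR1 call in gra3-D ended without any 1 of 4 arrays (WT replicates 1 and 3, gra3-D replicates 1 and 2; adjusted p up to 0.11), and those of AT4G40080 ended without any 1 of 5 arrays in gra1-D (up to 0.166) and without WT replicate 2 or gra3-D replicate 1 in gra3-D (up to 0.0559). The call of AT4G40080 in gra1-D also ended with the replicate block, with all arrays or without those of gra3-D, with an intensity trend and with gra1-D and wild-type arrays alone (up to 0.0636).

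**Figure D1:**
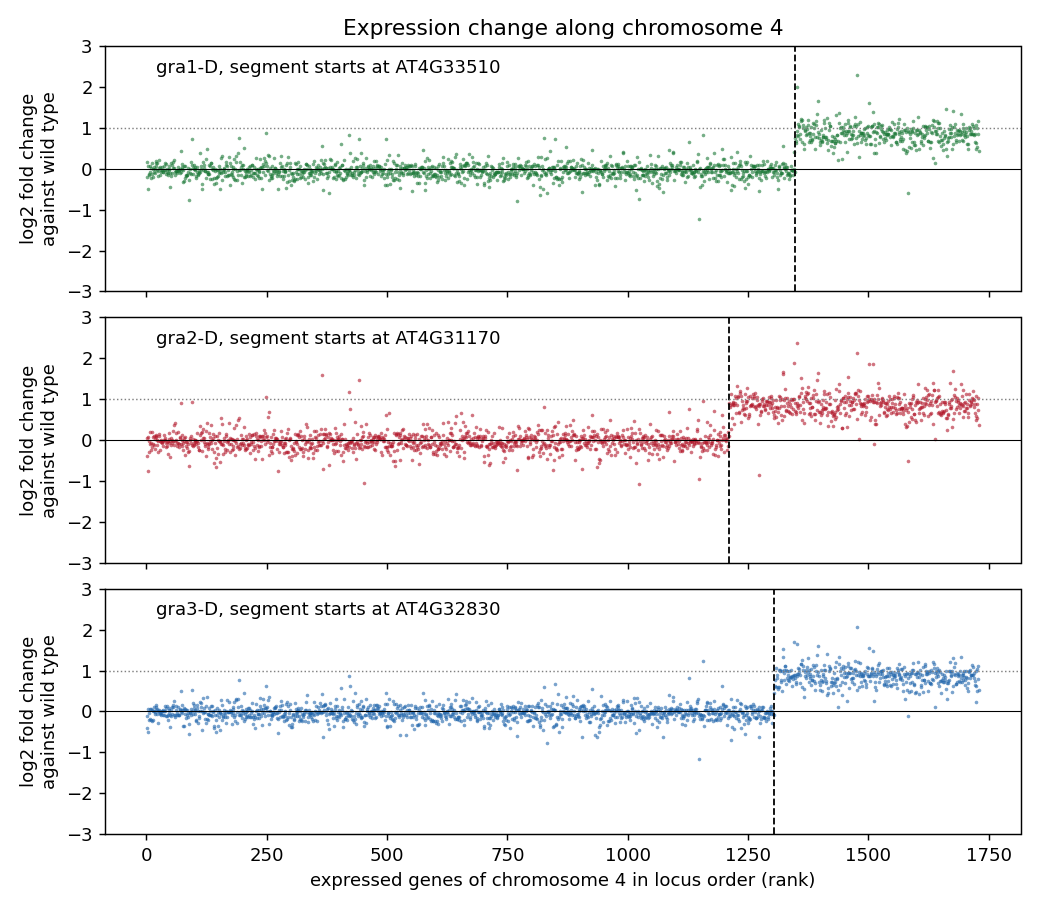
Log2 fold change against wild type (y axis) of each expressed gene of chromosome 4 in the order of the loci (x axis, rank), with 1 panel per mutant, a dashed line at the first gene of the raised segment and a dotted line at a log2 change of 1. Right of the dashed line the median shift per array averages 0.90 in gra1-D and 0.91 in gra2-D and gra3-D.

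The 3 starting points divided the region into 3 parts. The part from AT4G31170 to AT4G32810 was higher in gra2-D only, at 1.89-fold (log2 shift 0.92 ± 0.0043, SD, n = 3; 94 expressed genes), with gra1-D at 0.012 ± 0.017 and gra3-D at -0.018 ± 0.014. It includes WRKY18, a defence transcription factor gene that rose in gra2-D by 0.74 ± 0.10 (SE, adjusted p = 0.000202; a lower bound, since its wild-type mean log2 value of 4.79 lay close to background), and AT4G31805, the stomatal polarity gene POLAR, which rose by 0.63 ± 0.12 (adjusted p = 0.00241). The part from AT4G32830 to AT4G33500 (43 expressed genes) was higher in gra2-D at 0.89 ± 0.038 and in gra3-D at 0.90 ± 0.024 (SD, n = 3), and stood at -0.0094 ± 0.021 in gra1-D. It includes HB-8, a homeobox gene of procambium, which rose by 0.56 ± 0.083 in gra2-D and 0.60 ± 0.083 in gra3-D. The part from AT4G33510 onward stood at 0.90, 0.90 and 0.91 in the 3 mutants. Carriers and other arrays differed by 0.92 in the part of gra2-D (exact permutation p = 0.00909 over 220 splits), by 0.90 in the part of gra2-D and gra3-D (exact permutation p = 0.00217 over 924 splits) and by 0.90 in the part of all 3 mutants (exact permutation p = 0.00909 over 220 splits). These p-values are the smallest the splits allow, and the bounds came from the same arrays.

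**Figure D2:**
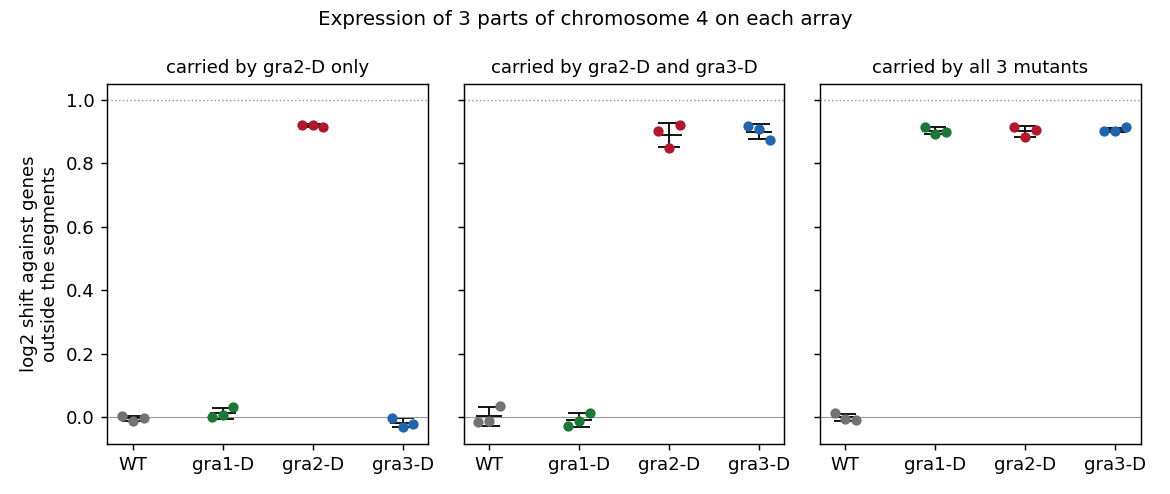
Log2 shift of the median expressed gene against genes outside the segments (y axis) on each of 12 arrays by group (x axis), in 3 panels for the 3 parts of chromosome 4; points are arrays, bars show the mean and SD of 3 arrays, and the dotted line marks a log2 shift of 1. Carrier groups average 0.89 to 0.92 and the other groups -0.018 to 0.012.

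The size of the rise in the segment varied with the signal level of the genes. Segment genes with a mean log2 value of 8 to 10 stood at 0.95 ± 0.016 (SD, n = 3) in gra1-D (161 genes), 0.96 ± 0.0017 in gra2-D (218 genes) and 0.95 ± 0.0019 in gra3-D (181 genes). Genes at 10 to 12 stood at 0.85, 0.87 and 0.87, and the 14, 16 and 15 genes at 12 or more at 0.59, 0.57 and 0.58. Genes at 5 to 6 stood at 0.43, 0.48 and 0.50, and those under 5, close to the array background, at 0.051, 0.065 and 0.054. The outer deciles of single expressed genes lay at 1.56-fold and 2.22-fold in gra1-D, at 1.53-fold and 2.25-fold in gra2-D and at 1.54-fold and 2.2-fold in gra3-D.

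**Figure D3:**
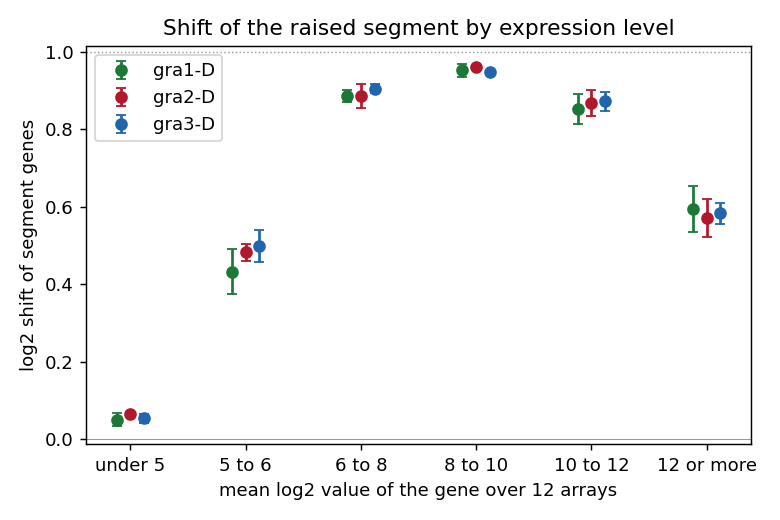
Log2 shift of the segment genes against genes outside at the same level (y axis) by the mean log2 value of the gene over 12 arrays (x axis, 6 classes); points are means of 3 arrays per mutant, bars are SD, and the dotted line marks a log2 shift of 1. Genes at 8 to 10 stand at 0.95 to 0.96 and genes at 12 or more at 0.57 to 0.59.

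Single genes inside the segment departed from its median change, which was 0.85 in gra1-D and 0.87 in gra2-D and gra3-D on the log2 scale. BT5, which encodes a BTB protein, was furthest below it in gra1-D, with a log2 change of -0.59 ± 0.29 (SE) against wild type and a departure of -1.44 (adjusted p = 0.00812). The repressor gene MYB4 (0.14 ± 0.13, departure -0.71) and the catalase gene CAT2 (AT4G35090; 0.24 ± 0.13, departure -0.61) were also below it in gra1-D, CAT2 at a mean log2 value of 13.0, in the brightest class of genes. In gra2-D, the auxin gene IAA29 (-0.85 ± 0.36) and the brassinosteroid enzyme gene ROT3 (-0.10 ± 0.14) departed by -1.72 and -0.97 (adjusted p = 0.0047 and 0.000496). MYB4 departed by -0.78 and AT4G40000 by -0.65 in gra3-D (adjusted p = 0.00184 and 0.00156). Above the median, KCS16, a fatty acid elongation gene, departed by 0.81 in gra1-D and 0.72 in gra3-D, and CRH1 (AT4G36280), a gene of the MORC family, by 1.0 in gra2-D (adjusted p = 2.07e-05). AT4G36010 departed by 0.75, 0.97 and 0.68 in the 3 mutants, and AT4G33490 by 1.02 in gra2-D and 0.82 in gra3-D. AT4G36010 lost its call in gra3-D without WT replicate 3 or gra3-D replicate 2 (adjusted p up to 0.0704).

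By limma, adjusted over the expressed segment genes, 62 of 383 genes departed in gra1-D (33 below, 29 above), 130 of 520 in gra2-D (81 below, 49 above) and 71 of 426 in gra3-D (46 below, 25 above). In all 3 mutants 40 genes departed the same way, 22 of them below. The 3 mutants share the wild-type arrays, whose errors enter all 3 departures, so the 40 have no independent control. Over all loci of the segment, expressed or not, limma called 0 lower than wild type in each mutant, against 1, 4 and 2 at an unadjusted p under 0.05. Among the expressed genes alone, 0, 1 and 0 were lower at that unadjusted p. With the replicate block, 94 genes departed in gra1-D. The counts fell to 31 without gra1-D replicate 1 and 38 without gra1-D replicate 3, to 83 in gra2-D without WT replicate 2, and in gra3-D to 45, 35, 31 and 37 without WT replicates 2 and 3 and gra3-D replicates 2 and 3.

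Comparing gra1-D with wild type asked what else differed beside the raised segment. Outside the segments, the largest rise was that of CDPK2 (AT1G35670), a calcium-dependent protein kinase gene, at 4.34-fold (log2 2.12 ± 0.12, SE, n = 3 per group). Its wild-type mean log2 value was 4.84, close to background, so its folds are lower bounds. AT5G03545 rose 3.56-fold, AT1G80130 2.86-fold, AT1G68600 by 1.46 ± 0.20, AT1G52000 2.67-fold, AT1G27030 2.45-fold and the galactinol synthase gene GolS3 2.31-fold. The largest fall was that of AT5G24240, at -3.41 ± 0.093 on the log2 scale, followed by CNGC12, a cyclic nucleotide-gated channel gene (-2.56 ± 0.12), AT2G05540 (-2.17 ± 0.24) and QQS, a gene that affects starch content (-2.07 ± 0.13). AT5G01870 (-1.63), the actin-related gene ARP9 (-1.57), AT3G62950 (-1.51) and the thionin gene THI2.2 (-1.50) fell as well. The gra1-D mean log2 values of AT5G24240 (4.67) and AT3G62950 (4.86) lay close to background, so these falls are lower bounds. In the segment, AT4G33550 rose 4.02-fold, KCS16 3.17-fold, AT4G36010 by 1.60 ± 0.16 and AT4G38950 2.73-fold. PSAT, a serine synthesis gene, rose by 2.3 ± 0.62 with adjusted p = 0.0487, a call that ended without any 1 of 4 of the 6 arrays (adjusted p up to 0.15). It also ended with a further quantile normalization, with either centring of the arrays, with array weights and with gra1-D and wild-type arrays alone (up to 0.104).

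Limma called 1160 loci changed in gra1-D, 586 higher and 574 lower. Of these, 401 higher loci lay in the raised segment, and 749 (184 higher, 565 lower) lay outside the segments of all 3 mutants. With each array centred on the chromosomes without a segment, 994 loci were called, 658 higher and 336 lower. The share of higher loci, 50.5% with all arrays, was 55.6% to 63.1% without any 1 wild-type or gra1-D array. With the replicate block fitted without the gra3-D arrays, an alternative added after seeing the data, 1820 were called (804 higher, 1016 lower). Outside the segments the count was 411 to 481 without any 1 of WT replicates 1, 2 and 3 and gra1-D replicates 1 and 3. The median log2 change outside the segments was -0.048 in gra1-D, -0.039 in gra2-D and -0.036 in gra3-D.

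In the segment of gra1-D, CYCD3;1, a D-type cyclin of the G1 phase, rose 1.98-fold (log2 0.99 ± 0.098), while CYCD3;3 and CYCD3;2 on other chromosomes fell by 0.33 and 0.27. Of 9 D-type cyclins 2 rose and 2 fell (2 and 5 adjusted over the list alone). Of 33 leaf size regulators 3 rose and 2 fell (3 and 2 adjusted over the list alone): GRF2 (AT4G37740; 0.96 ± 0.067), SPT (0.80 ± 0.093) and ANT, which prolongs organ growth (0.66 ± 0.088), rose in the segment, and CYP78A5 fell by 0.56. AN3, a partner of growth-regulating factors, stood at -0.12 ± 0.12 (adjusted p = 0.695). The segment genes ROT3 (0.39 ± 0.14, adjusted p = 0.146) and CYCB2;2 (0.74 ± 0.23, adjusted p = 0.0837) were not called. Of 17 mitotic genes only CYCB1;1, in the segment, changed, with 0.45 ± 0.12 (2 higher and 3 lower adjusted over the list alone). Of 23 cell wall loosening genes XTH7, in the segment, rose by 1.0 ± 0.11 and EXPA16 fell by 0.66 ± 0.12 (1 and 1 adjusted over the list alone). SPT in wild type (mean log2 value 4.93) and EXPA16 in gra1-D (4.54) lay close to background, so their changes are lower bounds. The calls of CYCD3;2, CYCD3;3, CYP78A5 and CYCB1;1 ended without any 1 of 4 or 5 of the 6 arrays, with adjusted p up to 0.091, 0.118, 0.0898 and 0.148. That of CYCB1;1 also ended with the replicate block and with gra1-D and wild-type arrays alone (up to 0.065), and that of CYP78A5 with the latter (0.0675). Those of CYCD3;2 and CYCD3;3 also ended with arrays centred on chromosomes without a segment and with gra1-D and wild-type arrays alone (up to 0.0679 and 0.0778).

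Of 12 cold and drought genes in gra1-D 2 rose (3 adjusted over the list alone), LTI78, also known as RD29A (1.02 ± 0.19), and the dehydrin gene ERD10 (0.52 ± 0.081). Of 11 jasmonate genes 2 rose (3 adjusted over the list alone), led by LOX2 (0.57 ± 0.091). Among 11 gibberellin and brassinosteroid genes GA3OX1, which makes active gibberellin, rose by 0.68 ± 0.12 and BR6OX2, which makes brassinosteroid, fell by 0.60 ± 0.12 (1 and 2 adjusted over the list alone). Of 12 cytokinin response genes 3 fell (4 adjusted over the list alone), among them the type-A response regulators ARR15 (-0.46 ± 0.12) and ARR4 (-0.26 ± 0.067). Of 18 auxin response genes SAUR15, in the segment, rose by 0.60 ± 0.098 and DFL1 fell by 0.73 ± 0.17 (1 and 1 adjusted over the list alone). Of 13 stomatal lineage markers only SDD1, a protease gene that limits stomatal density, rose, by 0.68 ± 0.089 (1 adjusted over the list alone). The calls of ARR15 and ARR4 ended without any 1 of 6 and 5 arrays (adjusted p up to 0.119 and 0.127), and that of DFL1 without WT replicate 1 or 3 (up to 0.0824). ARR4 also lost its call with a further quantile normalization, with either centring of the arrays and with gra1-D and wild-type arrays alone (adjusted p up to 0.107), and DFL1 with the latter (0.0767).

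Of 17 circadian clock genes in gra1-D, the RNA-binding protein gene CCR1 (AT4G39260), in the segment, rose by 0.66 ± 0.12 and RVE1 fell by 0.91 ± 0.23 (1 and 1 adjusted over the list alone). Of 7 shade and light signalling genes HFR1 rose by 0.75 ± 0.19 (2 adjusted over the list alone), and of 14 flavonoid genes the anthocyanin regulator PAP1 (AT1G56650) rose by 1.17 ± 0.29 (1 adjusted over the list alone). Of 10 vascular markers XCP1, in the segment, rose by 0.72 ± 0.12 (1 higher and 3 lower adjusted over the list alone). Of 16 floral markers FLC, a repressor of flowering, fell by 0.81 ± 0.18 and SPL4 by 0.29 ± 0.077 (2 lower adjusted over the list alone). The mean log2 values of FLC (4.45) in gra1-D and PAP1 (AT1G56650, 4.59) in wild type lay close to background, so their changes are lower bounds. SPL4 lay close to background in both groups (4.27 in gra1-D), so the size of its fall is uncertain. By limma 0 of 6 cytosolic ribosomal protein genes, 15 salicylate defence genes, 14 DNA replication genes, 8 CDK inhibitors and 13 root markers changed, against 2, 4, 1, 0 and 0 at an unadjusted p under 0.05; 1 ribosomal gene was lower adjusted over the list alone and 0 of the others. The calls of RVE1, HFR1, PAP1, FLC and SPL4 ended without any 1 of 4 or 5 of the 6 arrays, with adjusted p up to 0.147, 0.118, 0.13, 0.0799 and 0.169. SPL4 also lost its call with a further quantile normalization, either centring of the arrays, an intensity trend and gra1-D and wild-type arrays alone (adjusted p up to 0.116), and RVE1 with the latter (0.0711).

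As a set in gra1-D, the stomatal lineage markers were called higher by camera (median log2 change 0.18, adjusted p = 0.0233; adjusted p = 0.735 with an estimated correlation). That call ended without WT replicate 3 (adjusted p = 0.0613), gra1-D replicate 1 (0.0996) or gra1-D replicate 2 (0.0864). Fry, which tests a list against no change, did not call the list (adjusted p = 0.106). The other 28 lists had adjusted p from 0.0857 to 0.851. With members and background outside every segment, camera also called D-type cyclins (adjusted p = 0.00562) and the 6 measured ribosomal protein genes of the list (0.0322) lower. It called cold and drought (0.0144), jasmonate (0.0144), flavonoid (0.0144) and shade and light signalling genes (0.0441) higher. With all members and an estimated correlation, these 6 lists had adjusted p from 0.735 to 0.822. Median, mean and test differed in sign for cell wall loosening genes (0.0013, 0.04, lower), photosynthesis genes (0.0038, -0.0072, higher), shoot meristem markers (0.0039, -0.016, higher) and trichome genes (-0.06, 0.02, lower).

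In gra2-D against wild type, CDPK2 again had the largest rise outside the segments, at 4.12-fold (log2 2.04 ± 0.12, SE, n = 3 per group), followed by AT1G68600 (3.07-fold), the defence gene AZI1 (log2 1.59 ± 0.44, 3.01-fold), AT1G80130 (2.95-fold), the defence gene ACD6 (log2 1.46 ± 0.36, 2.76-fold), PAP1 (AT1G56650; 2.72-fold), the MADS-box flowering repressor MAF5 (2.57-fold) and AT1G52000 (2.54-fold). Wild-type mean log2 values of CDPK2 (4.84), PAP1 (4.59) and MAF5 (3.7) lay close to background, so their folds are lower bounds and their ranks uncertain. The largest falls were those of AT5G24240 (-3.11 ± 0.093), AT3G62950 (-2.26 ± 0.22), AT2G05540 (-2.02 ± 0.24), AT3G02480 (-1.79 ± 0.40), ARP9 (-1.61 ± 0.088), RVE1 (-1.55 ± 0.23) and AT3G16670 (-1.50 ± 0.31). The gra2-D mean log2 values of AT5G24240 (4.97), AT3G62950 (4.11) and AT3G02480 (4.4) lay close to background, so these falls are lower bounds. In the segment, AT4G33550 rose 5.19-fold, AT4G33490 3.71-fold, CRH1 3.65-fold and AT4G36010 3.6-fold. Limma called 2383 loci changed, 1089 higher and 1294 lower, with 563 of the higher ones in the raised segment and 1820 (526 higher, 1294 lower) outside. With arrays centred on chromosomes without a segment the majority turned, with 1198 higher and 1029 lower. It also turned without any 1 of WT replicates 1, 2 and 3 and gra2-D replicates 2 and 3 (50.6% to 54.8% higher). With gra2-D and wild-type arrays alone it turned as well (51.5% higher), but not without gra2-D replicate 1 (45.7%). The count outside was 1212 without WT replicate 1 and 1212 without gra2-D replicate 2. The calls of AZI1 and ACD6 ended without any 1 of 3 and 2 of the 6 arrays, with adjusted p up to 0.101 and 0.0766, WT replicate 1 among them for both. That of AZI1 also ended with gra2-D and wild-type arrays alone (adjusted p = 0.0827).

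In gra2-D, CYCD3;3 fell by 0.65 ± 0.083 and CYCD3;2 by 0.61 ± 0.066, and CYCD3;1, in the segment, rose by 0.65 ± 0.098. Of 9 D-type cyclins 2 rose and 2 fell (2 and 3 adjusted over the list alone). Of 17 mitotic genes 2 rose and 5 fell (3 and 6 adjusted over the list alone), with AUR1, in the segment, at 0.54 ± 0.11 and CYCB2;4 at -0.42 ± 0.092; CYCB1;1 stood at 0.40 ± 0.12 (adjusted p = 0.0441, up to 0.156 without any 1 of 4 of the 6 arrays). That call also ended with the replicate block, with all arrays or without those of gra3-D, and with gra2-D and wild-type arrays alone (adjusted p up to 0.08). Of 8 CDK inhibitors SIM fell by 0.36 ± 0.085 (1 adjusted over the list alone), a call lost without WT replicate 2 or 3 or gra2-D replicate 3 (adjusted p up to 0.0672). Of 33 leaf size regulators 3 rose and 2 fell (3 and 2 adjusted over the list alone), with GRF2 (AT4G37740) at 0.92 ± 0.067, SPT at 0.63 ± 0.093 (a lower bound, as in gra1-D) and ANT at 0.52 ± 0.088 in the segment; AN3 stood at -0.22 ± 0.12 (adjusted p = 0.33). Of 23 cell wall loosening genes 2 rose (2 adjusted over the list alone), led by XTH7, in the segment (1.05 ± 0.11).

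Of 12 cytokinin response genes in gra2-D 4 fell (6 adjusted over the list alone), with ARR15 at -0.86 ± 0.12, ARR6 at -0.55 ± 0.11 and ARR4 at -0.43 ± 0.067. Of 18 auxin response genes 1 rose and 4 fell (1 and 5 adjusted over the list alone), with IAA1 at -1.06 ± 0.14 and the homeobox gene HAT2 at -0.73 ± 0.15. Of 11 gibberellin and brassinosteroid genes 1 rose and 3 fell (1 and 4 adjusted over the list alone), with GA3OX1 at 1.01 ± 0.12, BR6OX2 at -0.68 ± 0.12 and GA20OX1 at -0.52 ± 0.095. Of 12 cold and drought genes 3 rose (3 adjusted over the list alone), with LTI78 at 1.09 ± 0.19 and ERD10 at 0.84 ± 0.081. Of 15 salicylate defence genes 4 rose (4 adjusted over the list alone), including WRKY18 in the segment and WRKY70 (1.18 ± 0.30, adjusted p = 0.0209, up to 0.0909 without WT replicate 1 or gra2-D replicate 2 or 3). Of 11 jasmonate genes AOS and LOX2 rose (2 adjusted over the list alone), by 0.40 ± 0.091 and 0.38 ± 0.091, calls that ended without WT replicate 2 or gra2-D replicate 3 (adjusted p up to 0.0538 and 0.0581).

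Of 13 stomatal lineage markers in gra2-D 3 rose (6 adjusted over the list alone), with AT4G31805 (POLAR) in the segment and SDD1 at 0.40 ± 0.089. Of 16 floral markers 3 fell (3 adjusted over the list alone), with the flowering promoters AGL20, also known as SOC1, at -0.83 ± 0.15 and SPL3 at -0.62 ± 0.13. Of 17 circadian clock genes RVE1 fell and CCR1 (AT4G39260), in the segment, rose by 0.94 ± 0.12 (1 and 1 adjusted over the list alone). Of 14 flavonoid genes 3 rose and 1 fell (3 and 2 adjusted over the list alone), led by PAP1 (AT1G56650), at 1.44 ± 0.29. Of 10 vascular markers 2 rose and 2 fell (2 and 4 adjusted over the list alone), with XCP1 and HB-8 higher in the segment. Of 6 ribosomal protein genes 3 fell (3 adjusted over the list alone), led by AT2G36170 (-0.41 ± 0.077). PIF4 rose alone among 7 shade and light signalling genes, by 0.31 ± 0.087 (1 adjusted over the list alone; adjusted p up to 0.125 without any 1 of 4 of the 6 arrays and 0.0572 with gra2-D and wild-type arrays alone). PYK10 fell alone among 13 root markers, by 0.54 ± 0.12 (1 adjusted over the list alone; adjusted p = 0.0526 without gra2-D replicate 3). By limma 0 of 14 DNA replication genes changed, against 2 at an unadjusted p under 0.05 and 0 adjusted over the list alone. As a set they were called lower by fry (adjusted p = 0.0281) but not by camera (adjusted p = 0.152).

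As sets in gra2-D, camera called the cytokinin response genes lower (median log2 change -0.36, adjusted p = 0.00225; adjusted p = 0.487 with an estimated correlation) and the cold and drought genes higher (0.25, adjusted p = 0.0135; adjusted p = 0.509 with an estimated correlation). It called the stomatal lineage markers higher (0.22, adjusted p = 0.0135, and 0.487 with an estimated correlation). The 6 measured ribosomal protein genes were called lower (-0.26, adjusted p = 0.0252, and 0.487 with an estimated correlation). This last list holds only loci that the gene table names so, and does not stand for ribosomal protein genes as a class. Without gra2-D replicate 2 the cold and drought genes (adjusted p = 0.17) and the ribosomal protein genes (0.147) lost their calls, and the latter also without WT replicate 2 (0.0774) and among genes of a mean log2 value of at least 6 (0.0881). The other 25 lists had adjusted p from 0.152 to 0.993. Fry, which tests a list against no change, called 9 lists in gra2-D, these 4 among them. It also called D-type cyclins (adjusted p = 0.0119), DNA replication genes (0.0281), gibberellin and brassinosteroid genes (0.04) and trichome genes (0.0281) lower. Salicylate defence genes were called higher by fry (adjusted p = 0.0441). With members and background outside every segment, camera also called D-type cyclins and mitotic genes lower (adjusted p = 0.00126 each; with all members and an estimated correlation, adjusted p = 0.487 and 0.781). Median, mean and test differed in sign for leaf size regulators (-0.013, 0.04, higher), cell wall loosening genes (-0.016, 0.12, higher), heat shock genes (-0.03, 0.03, lower) and floral markers (0.03, -0.06, lower).

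In gra3-D against wild type, CDPK2 rose 4.30-fold (log2 2.1 ± 0.12, SE, n = 3 per group), AT1G68600 3.00-fold, AT1G80130 2.61-fold, AT5G03545 2.60-fold, AT1G52000 2.28-fold and AT1G27030 and AT3G05640 2.1-fold each. The largest falls outside the segments were those of AT5G24240 (-3.45 ± 0.093), QQS (-2.49 ± 0.13), bHLH39, a regulator of iron uptake (-1.94 ± 0.40), AT2G05540 (-1.90 ± 0.24), AT5G01870 (-1.55 ± 0.18) and ARP9 (-1.47 ± 0.088). CDPK2 in wild type (mean log2 value 4.84) and AT5G24240 in gra3-D (4.63) lay close to background, so their changes are lower bounds. NAS3, a nicotianamine synthase gene, rose by 1.14 ± 0.26, a call that ended without any 1 of 4 of the 6 arrays (adjusted p up to 0.0839). In the segment, AT4G33490 rose 3.23-fold, AT4G33550 3.12-fold, KCS16 3.01-fold, AT4G36010 2.93-fold and AT4G33040 2.88-fold. Limma called 1269 loci changed, 651 higher and 618 lower, with 460 of the higher ones in the raised segment and 801 (190 higher, 611 lower) outside. With arrays centred on chromosomes without a segment there were 722 higher and 478 lower. The share of higher loci, 51.3% with all arrays, was 58.0% to 65.7% without any 1 wild-type or gra3-D array. The total was 817 without gra3-D replicate 2, and the count outside was 377 to 532 without any 1 of WT replicates 1, 2 and 3 and gra3-D replicates 2 and 3.

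In the segment of gra3-D, GRF2 (AT4G37740) rose by 0.95 ± 0.067, SPT by 0.82 ± 0.093 (a lower bound, as in gra1-D), CYCD3;1 by 0.74 ± 0.098 and ANT by 0.71 ± 0.088, while ROT3 (0.26 ± 0.14, adjusted p = 0.374) and CYCB2;2 (0.66 ± 0.23, adjusted p = 0.124) were not called. Of 33 leaf size regulators 3 rose and 2 fell (3 and 2 adjusted over the list alone), the largest fall being that of ATG2 (AT3G51800), the growth regulator EBP1, at -0.52 ± 0.084; AN3 stood at 0.09 ± 0.12 (adjusted p = 0.809). Of 9 D-type cyclins 2 rose and 2 fell (2 and 5 adjusted over the list alone), with CYCD3;3 at -0.37 ± 0.083 (adjusted p up to 0.0717 without WT replicate 1 or gra3-D replicate 1 or 3, and 0.0558 with gra3-D and wild-type arrays alone). Of 17 mitotic genes 1 rose and 3 fell (3 and 6 adjusted over the list alone), with AUR1, in the segment, higher and its paralog AUR2 lower at -0.55 ± 0.11; CYCB1;1 stood at 0.30 ± 0.12 (adjusted p = 0.179). TSO2, a ribonucleotide reductase gene, fell alone among 14 DNA replication genes, by 0.45 ± 0.085 (1 adjusted over the list alone). AT2G32710 (KRP4) fell alone among 8 CDK inhibitors, by 0.26 ± 0.070 (1 adjusted over the list alone; adjusted p up to 0.188 without any 1 of 5 of the 6 arrays). That call also ended with arrays centred on chromosomes without a segment, with an intensity trend and with gra3-D and wild-type arrays alone (adjusted p up to 0.118). Of 23 cell wall loosening genes XTH7 rose by 1.0 ± 0.11 and EXPA16 fell by 0.58 ± 0.12 (2 and 3 adjusted over the list alone), a lower bound at a gra3-D mean log2 value of 4.62.

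Of 12 cytokinin response genes in gra3-D 3 fell (4 adjusted over the list alone), led by ARR6 (-0.58 ± 0.11). Of 11 gibberellin and brassinosteroid genes 1 rose and 2 fell (1 and 2 adjusted over the list alone), with GA3OX1 at 0.83 ± 0.12 and BR6OX2 at -0.83 ± 0.12. Of 12 cold and drought genes 2 rose (3 adjusted over the list alone), LTI78 (0.95 ± 0.19) and ERD10 (0.47 ± 0.081). SAUR15, in the segment, rose alone among 18 auxin response genes, by 0.81 ± 0.098 (1 higher and 1 lower adjusted over the list alone). BGL2, also known as PR2, rose by 0.62 ± 0.14 among 15 salicylate defence genes (1 adjusted over the list alone) and JAZ1 by 0.64 ± 0.15 among 11 jasmonate genes (3 adjusted over the list alone). SDD1 rose by 0.52 ± 0.089 among 13 stomatal lineage markers (2 adjusted over the list alone). Of 16 floral markers SPL4 fell by 0.49 ± 0.077 and FLC by 0.70 ± 0.18 (2 adjusted over the list alone). The mean log2 values of FLC (4.56) in gra3-D and BGL2 (4.6) in wild type lay close to background, so their changes are lower bounds. SPL4 lay close to background in both groups (4.07 in gra3-D), so the size of its fall is uncertain. The calls of BGL2, JAZ1 and FLC ended without any 1 of 4 of the 6 arrays, with adjusted p up to 0.08, 0.0775 and 0.141. BGL2 also lost its call with gra3-D and wild-type arrays alone (adjusted p = 0.0693) and FLC with array weights (0.0553).

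Of 17 circadian clock genes in gra3-D CCR1 (AT4G39260), in the segment, rose by 0.68 ± 0.12 and RVE1 fell by 0.93 ± 0.23 (1 and 1 adjusted over the list alone), and HFR1 rose by 0.76 ± 0.19 among 7 shade and light signalling genes (1 adjusted over the list alone). The calls of RVE1 and HFR1 ended without any 1 of 4 and 3 of the 6 arrays (adjusted p up to 0.112 and 0.108), and that of HFR1 also with gra3-D and wild-type arrays alone (0.0633). Of 10 vascular markers HB-8 and XCP1, both in the segment, rose (2 higher and 1 lower adjusted over the list alone), XCP1 with adjusted p up to 0.0625 without WT replicate 2 or gra3-D replicate 3. Of 6 ribosomal protein genes AT2G36170 fell by 0.31 ± 0.077 (4 adjusted over the list alone; adjusted p up to 0.127 without any 1 of 5 of the 6 arrays), a call that also ended with arrays centred on chromosomes without a segment and with gra3-D and wild-type arrays alone (adjusted p up to 0.0538). By limma 0 of 14 flavonoid genes and 13 root markers changed, against 5 and 0 at an unadjusted p under 0.05; adjusted over the list alone, 4 flavonoid genes were higher and 1 lower and 0 root markers changed. PAP1 (AT1G56650) stood at 1.04 ± 0.29 (adjusted p = 0.0515).

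As sets in gra3-D, camera called the 6 measured ribosomal protein genes lower (median log2 change -0.26, adjusted p = 0.0159, and 0.627 with an estimated correlation). That call ended without WT replicate 2 (adjusted p = 0.0963). It covers only the loci that the gene table names so, not ribosomal protein genes as a class. The other 28 lists had adjusted p from 0.0505 to 0.915. With members and background outside every segment, camera also called D-type cyclins (adjusted p = 0.000717) and mitotic genes (0.0134) lower and jasmonate genes (0.00205), stomatal lineage markers (0.00205), flavonoid (0.0391) and cold and drought genes (0.0446) higher. With all members and an estimated correlation, these 6 lists had adjusted p from 0.627 to 0.795. Median, mean and test differed in sign for cell wall loosening genes (-0.01, 0.09, higher), photosynthesis genes (-0.003, 0.0013, higher), aliphatic glucosinolate genes (-0.016, -0.017, higher) and root markers (-0.017, 0.03, higher).

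In no mutant did limma call a change among photosynthesis genes (30 measured), leaf polarity genes (13), shoot meristem markers (10), trichome and epidermal patterning genes (6), heat shock genes (10), senescence and starvation genes (10), aliphatic glucosinolate genes (11), DNA damage response genes (8) or seed storage markers (11). Together these lists held 6, 9 and 9 members at an unadjusted p under 0.05 in gra1-D, gra2-D and gra3-D. Adjusted over the list alone, 1 trichome gene was lower in gra2-D, 1 meristem marker was higher in gra3-D and 0 other members changed. Camera gave these lists adjusted p from 0.238 to 0.993, and fry, which tests a list against no change, called the trichome genes lower in gra2-D (adjusted p = 0.0281). The photosynthesis gene GAPB stood at -0.22 ± 0.072, -0.23 ± 0.072 and -0.16 ± 0.072 (SE), the meristem marker CLV1 at 0.24 ± 0.080 in gra2-D and 0.28 ± 0.080 in gra3-D, and the DNA damage gene AT1G07500 at -0.10 ± 0.085, -0.15 ± 0.085 and -0.27 ± 0.085.

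Genes changed in all 3 mutants were sought as a common response. CDPK2 (2.12, 2.04 and 2.1), AT1G68600 (1.46, 1.62 and 1.58), AT1G80130 (1.52, 1.56 and 1.39), AT1G52000 (1.42, 1.34 and 1.19), AT1G27030, GolS3, AT5G03545 and the protein kinase gene CIPK25 (0.98, 1.18 and 1.02 ± 0.094) had the largest shared rises outside the segments on the log2 scale. AT5G24240, AT2G05540, AT3G62950, AT5G01870, ARP9, THI2.2 (-1.50, -1.36 and -1.30 ± 0.15), RVE1 and the cuticle-degrading enzyme gene CDEF1 (-1.23, -0.96 and -1.17 ± 0.22) had the largest shared falls. LTI78, ERD10, GA3OX1 and SDD1 rose and BR6OX2, ARR4 and CYCD3;3 fell in all 3 mutants, although the calls of ARR4 and CYCD3;3 in gra1-D ended without any 1 of 5 of the 6 arrays and under other settings (adjusted p up to 0.127 and 0.118). The changes of CDPK2, AT5G24240 and AT3G62950 are lower bounds in all 3 mutants. The call of CDEF1 in gra2-D had adjusted p = 0.05 without gra2-D replicate 3, that of ARR4 in gra3-D ended without any 1 of 4 of the 6 arrays (adjusted p up to 0.0869), and that of AT5G03545 in gra2-D ended without any 1 of 4 of the 6 arrays (adjusted p up to 0.121).

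In all, 783 loci changed the same way in the 3 mutants, 477 higher and 306 lower. With arrays centred on chromosomes without a segment there were 508 higher and 195 lower, and at a fold change of at least 1.5 there were 356 and 47. Outside the segments there were 397, 91 higher and 306 lower, against 0.0459 and 1.12 expected from independent lists. In 100 simulations of unchanged groups that share the wild-type arrays there were 0 on average. The simulated groups held no changed loci, so that 0 does not show how far errors of the shared wild-type arrays add to the overlap. The shared count outside was 216 to 254 without any 1 of WT replicates 1, 2 and 3, gra1-D replicate 1 and gra3-D replicate 2, and 264 without gra1-D replicate 3. Over the 20014 genes outside the segments, which are not independent replicates, log2 changes of gra1-D and gra2-D had a Pearson r of 0.762, those of gra1-D and gra3-D 0.815 and those of gra2-D and gra3-D 0.743. Shared wild-type arrays alone gave 0.499 to 0.5 in the simulations. Since all 3 contrasts share those 3 arrays, which cannot be divided into sets of at least 2, the overlap has no independent control.

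**Figure D4:**
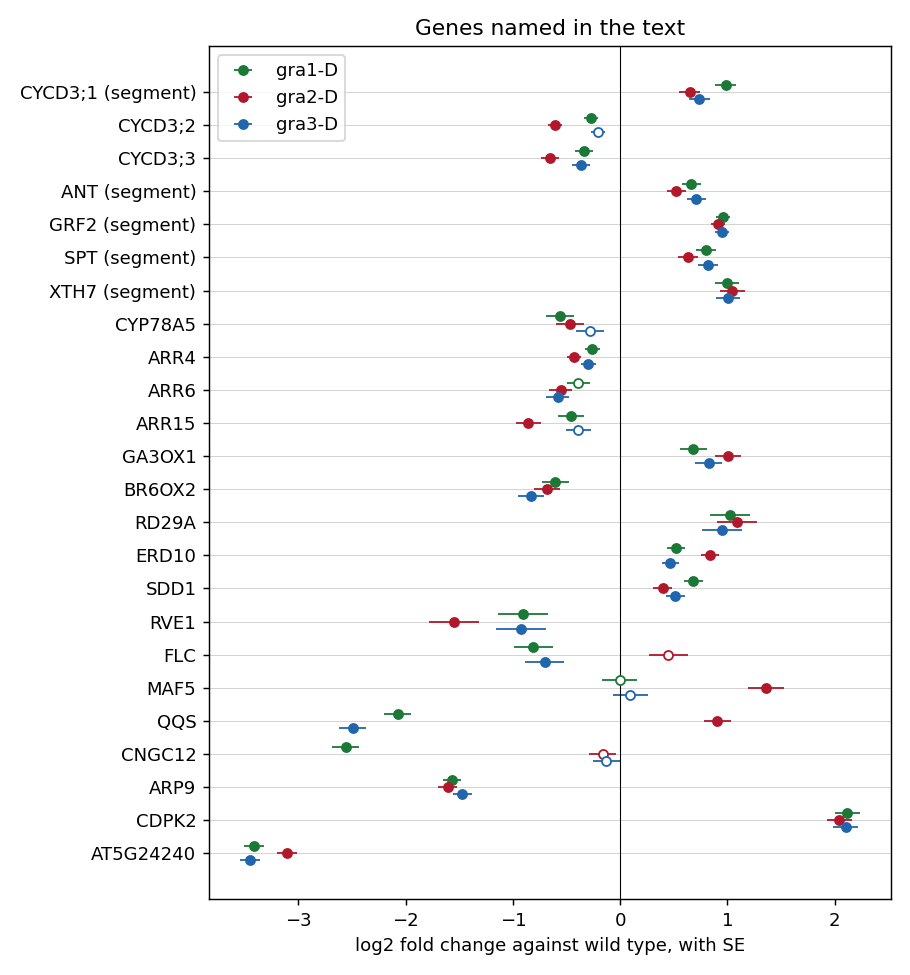
Log2 fold change against wild type (x axis) of 24 genes (y axis) in the 3 mutants, with SE bars, filled points for an adjusted p under 0.05 and open points otherwise; genes of the raised segment are marked. CDPK2 stands at 2.04 to 2.12 and AT5G24240 at -3.45 to -3.11 in all 3 mutants, whereas QQS stands at -2.07, 0.91 and -2.49.

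Direct tests of mutant against mutant asked which differences belong to single mutants. QQS was lower in gra1-D than in gra2-D (-2.98 ± 0.13 on the log2 scale, adjusted p = 6.44e-08) and 10.6-fold higher in gra2-D than in gra3-D (3.40 ± 0.13, adjusted p = 1.15e-08). CNGC12 was lower in gra1-D than in gra2-D (-2.40 ± 0.12) and than in gra3-D (-2.43 ± 0.12). MAF5 was higher in gra2-D than in gra1-D and gra3-D, with differences of -1.37 ± 0.16 and 1.27 ± 0.16, and FLC was higher in gra2-D than in gra3-D by 1.15 ± 0.18. Mean log2 values of MAF5 in gra1-D (3.69) and gra3-D (3.79) and of FLC in gra3-D (4.56) lay close to background, so these differences are lower bounds. AT1G43590 (1.37 ± 0.13), AT1G31680 (1.01 ± 0.15) and its neighbour AT1G31690 (0.87 ± 0.13) were higher in gra1-D than in gra2-D. AT1G43590 in gra2-D (mean log2 value 4.04) also lay close to background, so its difference from gra1-D is a lower bound. Its difference from gra3-D, where it lay under 5 too, is uncertain in size, and so are the ranks. AT1G43590 (-0.92 ± 0.13), AT5G62280 (-0.82 ± 0.16) and TPS9, a trehalose phosphate synthase gene (-0.80 ± 0.14), were lower in gra2-D than in gra3-D. The last 2 calls ended without any 1 of 5 of the 6 arrays (AT5G62280, adjusted p up to 0.141) and without gra2-D replicate 3 (TPS9, adjusted p = 0.0605).

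Limma called 256 loci different between gra1-D and gra2-D (50 higher in gra1-D, 206 lower), of which 148 lay among the 202 segment loci that gra1-D lacks and 105 (48 higher, 57 lower) outside the segments. The 50 became 27, 22 and 29 without gra1-D replicate 1, 2 or 3 and 35, 24 and 24 without gra2-D replicate 1, 2 or 3, while 182 to 202 were lower. Between gra1-D and gra3-D 46 loci differed, all lower in gra1-D, 44 of them among the 61 segment loci that gra1-D lacks; 389 loci were higher in gra1-D at an unadjusted p under 0.05. The other 2 were CNGC12 and NAC3 (AT3G29035), at -0.50 ± 0.082 with adjusted p = 0.0168, up to 0.127 without any 1 of 5 of the 6 arrays and up to 0.0574 with a further quantile normalization or each array centred on its median. Between gra2-D and gra3-D 185 loci differed (149 higher in gra2-D, 36 lower), 103 of them among the 141 segment loci that gra3-D lacks and 80 (46 higher, 34 lower) outside the segments. The 36 became 25, 18 and 15 without gra2-D replicate 1, 2 or 3 and 21, 22 and 20 without gra3-D replicate 1, 2 or 3, while 118 to 139 were higher.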

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

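The 3 tests of the fold below 2, the test of a wild-type array as the whole cause and the test of cross-hybridization were chosen only after the results were seen. Groups of 3 arrays are too small for the test of single outlying arrays, and no deposited values were left unanalysed.

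The differences below drew attention because a direct test told 2 mutants apart. On chromosome 4, the part raised in gra2-D alone stood 0.92 above the other arrays on the log2 scale, and the part raised in gra2-D and gra3-D stood 0.90 above them. Between gra1-D and gra2-D, CNGC12 (-2.40, adjusted p = 4.72e-07), QQS (-2.98), FLC (-1.26, adjusted p = 0.0014), MAF5 (-1.37) and NAC3 (AT3G29035; -0.55) were lower in gra1-D. FLC (4.45) and MAF5 (3.69) in gra1-D and AT1G43590 in gra2-D (4.04) lie at mean log2 values close to background, so their differences here are lower bounds. AT1G43590 (1.37), AT1G31680 (1.01), AT1G31690 (0.87), IAA1 (0.65, adjusted p = 0.0449), GA20OX1 (0.43, adjusted p = 0.0438) and CYCD3;2 (0.33, adjusted p = 0.0187) were higher. Between gra1-D and gra3-D, CNGC12 (-2.43) and NAC3 (AT3G29035; -0.50) were lower in gra1-D.

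Between gra2-D and gra3-D, QQS (3.40), MAF5 (1.27), FLC (1.15) and the defence gene FMO1 (0.33, adjusted p = 0.0356) were higher in gra2-D. FLC and MAF5 in gra3-D lie close to background, at mean log2 values of 4.56 and 3.79, so their differences are lower bounds. AT1G43590 (4.04 in gra2-D) and FMO1 (3.83 in gra2-D and 3.5 in gra3-D) lie close to background in both groups. The size of the AT1G43590 and FMO1 differences is therefore uncertain. AT1G43590 (-0.92), AT5G62280 (-0.82), TPS9 (-0.80), IAA1 (-0.69, adjusted p = 0.0425), GA20OX1 (-0.48, adjusted p = 0.0271) and CYCD3;2 (-0.40, adjusted p = 0.00624) were lower. Several of these calls ended without any 1 of several of the 6 arrays. Between gra1-D and gra2-D they were IAA1 (6 arrays, adjusted p up to 0.19), GA20OX1 (4, up to 0.202) and CYCD3;2 (4, up to 0.0994). Between gra1-D and gra3-D NAC3 (AT3G29035) lost its call (5, up to 0.127), and also with a further quantile normalization or each array centred on its median (up to 0.0574). Between gra2-D and gra3-D they were IAA1 (5, up to 0.174), GA20OX1 (4, up to 0.148), FMO1 (5, up to 0.165), AT5G62280 (5, up to 0.141) and TPS9 (without gra2-D replicate 3, 0.0605).

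As sets, camera placed the cytokinin response genes lower in gra2-D than in gra1-D (gra1-D minus gra2-D, median 0.14, adjusted p = 0.00558; adjusted p = 0.509 with an estimated correlation) and than in gra3-D (-0.14, adjusted p = 0.0178; adjusted p = 0.702 with an estimated correlation). Leaf polarity genes were also lower in gra2-D than in gra1-D (gra1-D minus gra2-D, 0.10, adjusted p = 0.0121; adjusted p = 0.543 with an estimated correlation) and than in gra3-D (-0.11, adjusted p = 0.0243; adjusted p = 0.742 with an estimated correlation). Cold and drought genes were higher in gra2-D than in gra3-D (0.25, adjusted p = 0.0404; adjusted p = 0.849 with an estimated correlation). Trichome and epidermal patterning genes were lower (-0.12, adjusted p = 0.0404; adjusted p = 0.574 with an estimated correlation). Limma called no single member of these 4 lists different in these contrasts at the adjusted threshold, against 4 cytokinin and 2 leaf polarity genes between gra1-D and gra2-D, and 4 cytokinin, 1 leaf polarity, 2 cold and drought and 2 trichome genes between gra2-D and gra3-D, at an unadjusted p under 0.05. Adjusted over the list alone, 3 cytokinin genes were higher in gra1-D than in gra2-D, and 2 cytokinin genes were lower and 1 cold and drought gene higher in gra2-D than in gra3-D.

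The raised segment stood below a doubling in all 3 mutants. A common downward shift from the authors' normalization as the whole cause is excluded, since the shift taken against genes outside the segment reached at most 0.91. Probe signal near background and saturation may explain part of the gap: genes at 12 or more lay at least 0.36 below genes at 8 to 10 in every mutant, although only 14 to 16 genes lie in that class. Partial compensation of the extra copies cannot be told apart from a compressed array response, because genes at 8 to 10 stood at up to 0.96 and the response of the arrays at that level is not known. The number of copies per plant is not given in the labels.

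Outside the segments 397 loci changed the same way in all 3 mutants. A single aberrant wild-type array as the whole cause is excluded, since 59.95% of the loci were left in the lowest of the 3 counts without 1 wild-type array, but a contribution cannot be told apart from the loss of power because that count was 238. Cross-hybridization with the duplicated genes is excluded only for the loci that were lower, 77.1% of these, a share that depends on the scaling: with arrays centred on chromosomes without a segment, 195 shared loci were lower instead of 306. A second linked stretch of the genome is not favoured: the most crowded window of 50 expressed genes held 7 shared loci, against a median of 7 in 10000 random draws (permutation p = 0.527). A difference in growth or seed stock between wild type and all mutants is confounded with the groups, and an effect of the extra gene copies was not tested.

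More loci changed outside the segments in gra2-D (1820) than in gra1-D (749) or gra3-D (801). A single aberrant gra2-D array is excluded as the cause, since at least 1212 loci were called without any 1 of them. Less scatter in gra2-D could not raise its count alone through the SE, since the common fit gave each locus the same SE in every contrast. The ratio of SDs therefore decides nothing here. The median SD of gra2-D was 1.02 to 1.08 times that of the other groups, the highest ratio being 1.08 to gra3-D. The larger segment and differences in growth between the plants stay open as untested explanations.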

How the results depend on the processing

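The replicate block without the gra3-D arrays was added after the data were seen; the other alternatives were planned. Of 290 results for a named gene in a comparison, 215 were called, 142 of them under every alternative tried and 0 in the opposite direction anywhere. Of the called ones, 73 lost their call without some array and 36 under another setting, and 22 not called were called under some setting. Departures from the segment median are not part of this count. Of 87 list results, none that was called changed sign and none was called in the opposite direction. Lists that stayed without a call could change sign, such as the photosynthesis genes in gra1-D, higher by camera and lower by fry.

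Without 1 array at a time, changed loci numbered 794 to 965 in gra1-D, 1761 to 2070 in gra2-D and 817 to 1108 in gra3-D, 205 to 229 between gra1-D and gra2-D, 42 to 44 between gra1-D and gra3-D, 133 to 157 between gra2-D and gra3-D and 590 to 752 in all 3 mutants. Fewer arrays leave fewer degrees of freedom. The raised segment held 561, 763 and 621 to 622 loci, with shifts of 0.8966 to 0.9083, 0.9049 to 0.9152 and 0.9028 to 0.9096. Departing genes numbered 31 to 51, 83 to 124 and 31 to 64, and lists called 0 to 4, 2 to 5 and 0 to 3.

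With a fold change of at least 1.5, which removes smaller changes by construction, 491 loci were called in gra1-D, 789 in gra2-D, 550 in gra3-D, 169 between gra1-D and gra2-D, 122 between gra2-D and gra3-D and 403 in all 3 mutants. Outside the segments, gra1-D had 749 loci and gra3-D 801, because the segment genes were left out. With the replicate block, gra1-D had 1461 loci, 1132 of them shared with the 1160. With the block and without gra3-D arrays, which changes 2 choices, it had 1820, sharing 1138, and the cause was not tested. In gra2-D there were 2885 loci with the block and 3271 with the block and without gra3-D arrays, against 2383. With each array centred on chromosomes without a segment, the share of higher loci in gra1-D went from 50.5% to 66.2%. This setting moves each array by a constant, so the difference comes from offsets between arrays. The median log2 change outside the segments was -0.048 in gra1-D. What produced the offsets was not tested.

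The segment shift differed with the level of the genes; the cause was not tested here. It was 0.9173, 0.9283 and 0.9147 in gra1-D, gra2-D and gra3-D for genes at a mean log2 value of at least 8, 0.8753, 0.8795 and 0.8797 at 5 or more, and 0.7501, 0.7441 and 0.7742 for all genes. As a mean of the genes it was 0.8995 in gra3-D. Departing genes numbered 280, 412 and 298 with all genes tested, 43 in gra3-D at 8 or more, where fewer genes were tested, and 94 in gra1-D with the replicate block.

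Of the lists, camera with an estimated correlation called 0 in gra1-D, 0 in gra2-D and 0 in gra3-D, against 0, 1 and 1 at an unadjusted p under 0.05. Fry called 0 in gra1-D (5 unadjusted) and 9 in gra2-D. With members and background outside every segment, 7 lists were called in gra1-D and 7 in gra3-D, and with genes at a mean log2 value of at least 6, 3 and 2. The cause was not tested for these.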

Other observations

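The test of iron deficiency genes was chosen only after the result was seen, and the flowering, phosphate and neighbour genes named here were chosen after their values were seen. Of 5 flowering repressors looked up, MAF5 rose by 1.36 ± 0.16 (SE, n = 3 per group) and its neighbour MAF4 by 0.38 ± 0.07 in gra2-D (adjusted p = 0.00373). The mean log2 value of MAF5 over all arrays (4.06) lies close to background, so its rise is a lower bound. MAF4 (3.9 over all arrays) lies close to background in both groups, so the size of its rise is uncertain. FLC fell in gra1-D (-0.81) and gra3-D (-0.70), to mean log2 values close to background (4.45 and 4.56), so these falls are lower bounds, and stood at 0.45 in gra2-D (adjusted p = 0.148). SVP rose in gra3-D (0.26, adjusted p = 0.0302), a call not tried without single arrays. MAF1 and SVP were not called different between any 2 mutants (lowest adjusted p = 0.736 and 0.616). The flowering promoter FT stood at -0.06, 0.11 and -0.02 in gra1-D, gra2-D and gra3-D and was not called. Its mean log2 value over all arrays, 3.88, lies close to background, where a change could go unseen. The copper amine oxidase-like neighbours AT1G31680 and AT1G31690 stood at -1.46 and -1.26 in gra2-D and at -1.12 and -0.95 in gra3-D, all called, and at -0.45 (adjusted p = 0.117) and -0.39 (adjusted p = 0.108) in gra1-D.

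Of 9 phosphate response genes looked up, 3 rose in each mutant. The 9 were not sorted by their direction in a phosphate starvation response, so the 3 rises are no measure of such a response. SPX1 stood at 0.45, 0.36 and 0.39 (adjusted p = 0.0147, 0.0299 and 0.0298), PHO2 at 0.53, 0.39 and 0.39 (adjusted p = 0.0053, 0.0215 and 0.0328) and AT5G03545, a non-coding phosphate starvation transcript, at 1.83, 1.01 and 1.38. The calls of SPX1 and PHO2 were not tried without single arrays. That of AT5G03545 in gra2-D ended without any 1 of 4 of the 6 arrays (adjusted p up to 0.121). PAP17 (0.85, 0.77 and 0.68, adjusted p = 0.0845, 0.0798 and 0.178), SQD2 (-0.01, 0.04 and 0.01), SPX3 (-0.04, 0.03 and 0.00090), PHT1;4 (-0.01, -0.15 and -0.09), MGDC (0.03, 0.08 and -0.16) and PHO1;H1 (0.0078, 0.24 and 0.25) were not called, and no test of the group was run. SPX3, PHT1;4 and MGDC lie close to background, at mean log2 values of 4.01, 3.58 and 4.33 over all arrays, where a change could go unseen.

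Iron deficiency genes may be lower in gra3-D as a group, a hypothesis. Of 9 measured genes of a list of 12, bHLH39 (-1.94), BTS (-0.82, adjusted p = 0.0216) and FRO3 (-0.80, adjusted p = 0.000986) fell. The calls of BTS and FRO3 were not tried without single arrays. IRT1, a root gene, stood at -0.06, at a mean log2 value of 3.645 over all arrays, close to background, where a change could go unseen. Camera gave an unadjusted p = 0.000196 with the preset correlation and p = 0.122 with the estimated correlation of 0.503, so a group change cannot be told apart from correlated variation. The same tests by camera gave an unadjusted p = 7.91e-09 and an unadjusted p = 0.0281 between gra1-D and gra3-D, and an unadjusted p = 0.0105 and an unadjusted p = 0.27 between gra2-D and gra3-D, with lower levels in gra3-D. Against wild type the list was also lower in gra2-D (median -0.31, camera unadjusted p = 0.0378 and 0.364), with 0 members called. In gra1-D its median was -0.10 (camera unadjusted p = 0.611 and 0.82). Between gra1-D and gra2-D camera gave unadjusted p = 0.0115 and 0.275, with lower levels in gra2-D. Limma called no single member different between mutants, the lowest adjusted p being 0.115 for FRO3.

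CNGC12 fell in gra1-D alone against wild type. A loss of the locus that takes its neighbours along is excluded for the 5 expressed loci among the 8 nearest measured, SDH8 (-0.07), AT2G46420 (0.16), OXA1L (-0.04), AT2G46490 (0.22) and PI4K GAMMA 4 (-0.19), with adjusted p from 0.154. The other 3, WRKY46, CPC and GAUT2, lie close to background, at wild-type mean log2 values of 4.88, 4.76 and 4.09, and leave it untested there. The adjacent paralog CNGC11 is not in the deposited table.

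Signal level as the whole source of the departures inside the segment is excluded: against the median of their own level class, 46, 115 and 57 genes departed in gra1-D, gra2-D and gra3-D, and 35, 97 and 43 departed in both tests. Genes below the median went from 33, 81 and 46 to 19, 61 and 28, so level stays open as a source of part of them. Of the 33, 81 and 46, 9, 12 and 10 had a mean log2 value of 12 or more.

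Other splits of the arrays were tried for each count. The 10 splits of 6 arrays are too few for a share under 0.05, and 1 split, the real one, gave a count as large for changed loci and departing genes. Changed loci numbered 1160, 2383 and 1269 in gra1-D, gra2-D and gra3-D (highest other 0 in each), 256 between gra1-D and gra2-D (highest other 0), 46 between gra1-D and gra3-D and 185 between gra2-D and gra3-D (highest other 1 in each). Departing genes numbered 62, 130 and 71 (highest other 0 in each). Lists called numbered 1, 4 and 1 (highest other 5, 7 and 4), with 8, 4 and 8 of 10 splits giving as many. For loci changed in all 3 mutants, 1 of 100 relabelings of the 12 arrays, the real one, reached 783, and the highest other was 107. The 783 include loci of the raised segment, and the 397 outside were not counted on their own. The relabelings also ignored the pairing of replicate numbers described below, so they do not decide on the shared loci outside.

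Replicate numbers paired arrays across groups except replicates 1 and 3 of gra3-D. Deviations from group means over genes, which are not independent replicates, correlated at 0.35, 0.39 and 0.27 for replicates 1, 2 and 3 of wild type and gra1-D, at 0.33, 0.26 and 0.24 for wild type and gra2-D, and at -0.20, 0.23 and -0.09 for wild type and gra3-D. Replicate 1 of gra3-D correlated best with number 3 of the other groups, and replicate 3 with number 1. The main fit did not use this pairing, so variation shared by equal numbers stayed in its residual. The replicate block with all arrays took the gra3-D numbers as labelled. With that block 1461, 2885 and 1596 loci were called in gra1-D, gra2-D and gra3-D against wild type, against 1160, 2383 and 1269 in the main fit.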
